A study of Plecoglossus altivelis with 2 samples.

How the data were processed

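RNA sequencing was carried out on 2 libraries, 1 from ayu (Plecoglossus altivelis, a migratory fish that moves between rivers and the sea) larvae held in brackish water and 1 from larvae held in fresh water. Per the labels' protocols, RNA came from a mixture of 9 tissues taken after 4 weeks of acclimation: brain, gill, heart, intestine, kidney, liver, muscle, skin and spleen. Per the same protocols, polyadenylated RNA was enriched with oligo(dT) beads from DNase-treated total RNA, fragmented, copied into cDNA with random hexamers and amplified by PCR. The protocols name no step that marks the strand.

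The values were made by the authors. Per the file headers, each library has an estimated (expected) count, a TPM value and an FPKM value (both scaled by transcript length and by the size of the library) and the percent of its component taken by each transcript. The features are transcripts of an assembly, with identifiers made of a component, a subcomponent and a sequence number. The second identifier in the files, which drops the sequence number, is called a component here. The assembler, the aligner, the quantifier and their versions are not given in the sources used here. Per the file headers, an effective length is listed, and in the deposited files it equalled the transcript length for 145445 of 145445 transcripts. The deposited TPM and FPKM values were nonetheless not scaled by that length. Among transcripts with a TPM of at least 10 and at least 100 counts, the ratio of count to TPM followed the length minus 61.5 bases within 1% for 100% of 9263 transcripts in brackish water and of 8733 in fresh water, against 18.4% and 18.9% for the full length. The FPKM values gave the same 61.5 bases in both libraries, and what step made this correction is not given in the sources used here. The estimated counts deposited by the authors need not be whole and summed to 72013090 in brackish water and 72522809 in fresh water.

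A further table holds the authors' own comparison of the 2 libraries. Its log2 fold, p-value and FDR columns were deposited by the authors, and how the p-values were made is not given in the sources used here. The counts and FPKM values in it were equal to those of the library files for 133434 of 133434 transcripts. The 12011 transcripts left out of the authors' deposited table had an FPKM of 0 in both libraries. The log2 fold in the authors' deposited table, fresh over brackish, equalled the log2 ratio of the FPKM values within 1e-06 for 104470 of 104470 transcripts with a finite ratio. Its calls matched the rule of an FDR under 0.05 and an absolute log2 fold of at least 1 for 133434 of 133434 transcripts.

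Each salinity is represented by 1 library, so no spread between replicates exists, and no p-value of the present comparison is given. What was fixed before the data were examined was a rule of size. Estimated counts were rounded to whole numbers to compute TMM factors with edgeR 4.0.16 in R 4.3.3, and the counts themselves were scaled with these factors. A feature was called apart when its fold, with a pseudocount of 0.5, was at least 2 and its scaled count was at least 50 in the higher library. The intervals of folds are exact (Clopper-Pearson) binomial 95% intervals on the rounded counts and cover counting error only. They cover neither animals, tanks, tissue mixing nor library making, and reads from PCR without molecular identifiers are not independent molecules. A count of 0 was given the limit of 3 counts per library.

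Features seen in 1 library only had at least 10 counts there and 0 in the other library. A change of isoform share was called in components with at least 50 counts in each library when a transcript's share of the component's counts moved by at least 50 percentage points. Components were summed over their transcripts. Whole counts were tallied as even or odd from 1 to 41 in components with 1 transcript, with a weight of 0.5 on the 2 end values, so that a smooth slope gives an even share of 50%. This tally, the minimum of 100 scaled counts over both libraries, the sums over swapped transcripts and the comparison of the authors' p-values with FPKM were chosen after the data had been seen. The named transcripts are the 2 with the largest rise and the 2 with the largest fall among those with at least 200 scaled counts in the higher library.

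The files do not pair the identifiers with gene names and no annotation was used here, so 19 gene lists fixed beforehand (ion transport, tight junctions, osmolytes, hormones, stress, immunity, metabolism and tissue markers) were not analysed here, and no genome position is given. For the same reason transcripts that share reads with near-identical copies are not marked, and single transcripts are uncertain where a component holds several.

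The rule was tested on simulated counts for the 145445 transcripts, in which 200 had known folds. These were drawn only from transcripts with a mean level of at least 200 counts. The rates for known folds therefore do not cover transcripts nearer the rule's minimum of 50. For the comparison of brackish with fresh water it called 100% of 50 transcripts raised 3-fold and 0% of 50 raised 1.5-fold, and 0.0355% of 61964 transcripts with no simulated change. The simulated counts held counting error only, with no variation between animals, tanks or library preparations. They also held no error in the division of reads between transcripts. These rates therefore say nothing about such variation or error. Alternatives were DESeq2 1.42.0 size factors, scaling by total count, the ratio of the deposited TPM values, other count minimums, a 4-fold limit, a pseudocount of 5, a fold interval wholly beyond 2-fold, and sums over components. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.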

Results

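The study compared gene expression in ayu larvae kept in brackish water with that in larvae kept in fresh water, to find expression that goes with a change of salinity. The brackish water held 0.17 M NaCl, a salinity of 10 ppt, and both groups were kept at 20 to 22 °C for 4 weeks in groups of 20 fish. Each group was sequenced as 1 library of 9 mixed tissues. How many fish and tanks entered each mixture is not stated in the labels. The values below therefore describe 2 libraries, and none of the differences has a replicate check.

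The assembly held 145445 transcripts in 70911 components, and 17288 components held more than 1 transcript. The transcripts were 201 to 19352 bases long, with a median of 797 bases. The brackish water library had 72013090 estimated counts and the fresh water library 72522809. These totals were nearly equal, but they give the depth in fragments only if both libraries were counted alike. By counting error alone, a count of 0 allowed a level of up to 0.0417 CPM in brackish water and 0.0414 in fresh water. Counts above 0 were found for 125685 transcripts in brackish water and for 115813 in fresh water. At the level of components the numbers were 70540 in brackish water and 65601 in fresh water.

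The 2 libraries shared many of their most abundant transcripts. The 10 transcripts with the highest TPM took 12.7% of all TPM in brackish water and 13.9% in fresh water, and 6 of them were the same transcripts. The 100 highest took 34.0% and 35.4%, and 82 were shared. By estimated counts, which favour long transcripts, the 10 highest took 19.5% in brackish water and 13.7% in fresh water.

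The counts also differed in 1 set of 8 transcripts that share the leading number of their identifiers, singled out after its values were seen because it held the most counts of all. Its 8 transcripts, 17152 bases together, took 14.8% of the counts in brackish water and 5.24% in fresh water, which is 10677879 against 3801005 counts. The levels of all 8 were higher in brackish water after TMM scaling, but by unequal amounts. The longest, of 4632 bases, was 3.86-fold higher and one of 3061 bases was 5.32-fold higher, whereas one of 4455 bases was 1.14-fold higher. The counts outside this set came to 61335211 in brackish water and 68721804 in fresh water.

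Components, in which the counts of all transcripts were summed, differed less between the salinities than single transcripts did. Of 35291 components with at least 50 scaled counts in the higher library, 6446 were at least 2-fold apart. In brackish water 2896 components were higher and in fresh water 3550, and together they made up 18.3% of those compared. Of 70123 transcripts, 27271 were at least 2-fold apart, which is 38.9%, with 13692 higher in brackish water and 13579 higher in fresh water. The minimum itself raised these shares, because a feature with fewer than 100 scaled counts over both libraries passes it only when the libraries are unequal. Such features made up 3419 of the components compared, of which 2415 (70.6%) were 2-fold apart. With at least 100 scaled counts over both libraries, 4031 of 31872 components (12.6%) and 18854 of 60027 transcripts (31.4%) were 2-fold apart, 1868 of these components being higher in brackish water and 2163 in fresh water. Across 68246 components with at least 10 counts, the log2 levels in the 2 libraries had a Pearson correlation of 0.98 and a Spearman correlation of 0.84. Across 123476 transcripts these were 0.89 and 0.65, on the same log2(CPM + 1) scale. Both correlations are across features of the same 2 libraries, and features are not independent replicates.

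**Figure D1:**
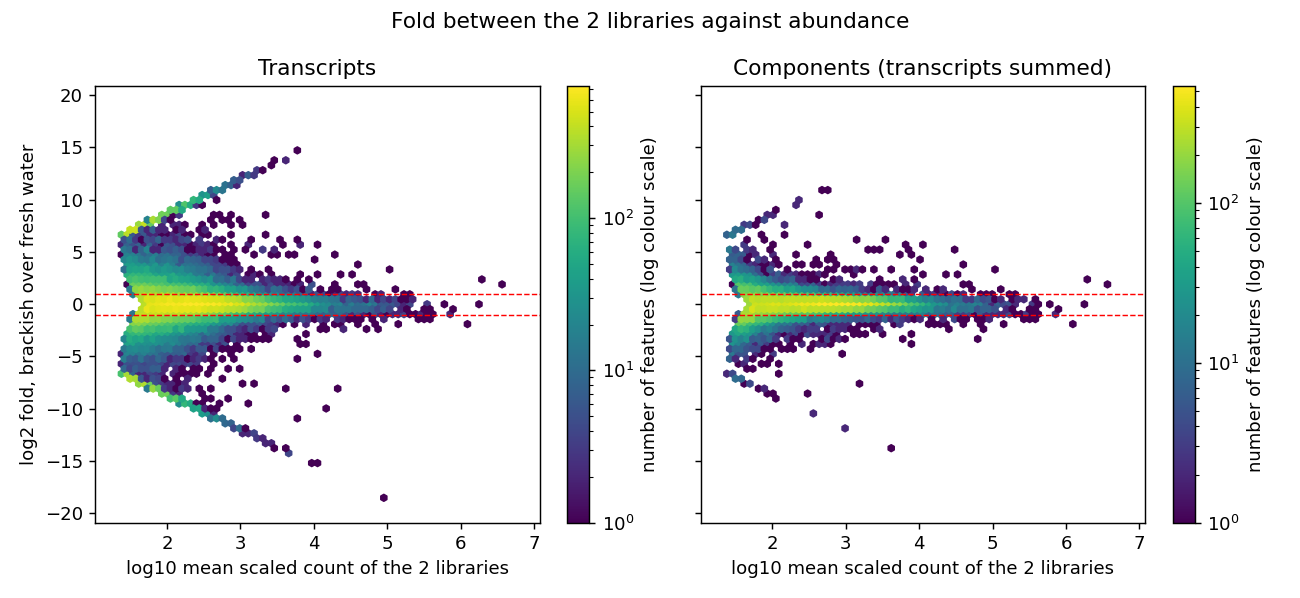
The log2 fold of brackish over fresh water (vertical axis) is plotted against the log10 mean scaled count (horizontal axis) for transcripts on the left and components on the right, with colour giving the number of features in each hexagon on a log scale and dashed lines at 2-fold. The 2 slanted edges are features with 0 counts in 1 library, and they hold far fewer components than transcripts.

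The share of components that differed depended on their abundance, here given from 100 counts upwards. Among 6637 components with 100 to 200 scaled counts over both libraries, 30.0% were at least 2-fold apart, 911 being higher in brackish water and 1081 in fresh water. From 200 to 1000 counts the share was 12.3% and from 1000 to 10000 counts it was 3.76%. It was 6.03% from 10000 to 100000 counts and 11.5% of the 183 components above 100000 counts. In that most abundant class, 17 components were higher in fresh water and 4 in brackish water, and the median log2 fold was -0.16. The median log2 fold of the 11321 components with 1000 to 10000 counts was 0.00.

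Of the 13095 components with at least 1000 counts over both libraries, 231 were at least 2-fold higher in brackish water and 312 at least 2-fold higher in fresh water. At 4-fold, 47 were higher in brackish water and 50 in fresh water. At 16-fold, 16 were higher in brackish water and 5 in fresh water. The typical difference was small, with a median absolute fold of 1.18.

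Most transcripts that were 2-fold apart belonged to components whose total was not. In components with more than 1 transcript, 22410 transcripts were at least 2-fold apart, and 1931 of them (8.62%) lay in a component that differed at least 2-fold in the same direction. For 20324 of them (90.7%) the component did not meet the rule, and for 155 it met it in the opposite direction. In 3669 components, at least 1 transcript was 2-fold higher in brackish water and another was 2-fold higher in fresh water. Among components with a single transcript, 4861 of 19385 transcripts were 2-fold apart, 2082 being higher in brackish water and 2779 in fresh water.

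The 4 transcripts named by the rule of largest change were all at 0 counts in 1 library. Transcript comp117130_c0_seq2, of 3554 bases, had 11932 counts in brackish water and 0 in fresh water, 4022-fold higher in brackish water on this setting. The total of its component, which holds 2 transcripts, was 1.39-fold higher in brackish water, with a 95% interval of 1.36 to 1.42 from counting error. Transcript comp123457_c0_seq5, of 2847 bases, had 8325 counts in brackish water and 0 in fresh water, 2806-fold higher in brackish water on this setting. The total of its component of 8 transcripts was 0.894 times the fresh water level (95% interval 0.870 to 0.918).

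In the opposite direction, comp126272_c0_seq1, of 5460 bases, had 170871 counts in fresh water and 0 in brackish water. On this setting it was 56322-fold higher in fresh water. Its component of 2 transcripts was 1.60-fold higher in fresh water. Transcript comp124678_c2_seq7, of 2750 bases, had 22096 counts in fresh water and 0 in brackish water, 7283-fold higher in fresh water on the same setting. Its component of 8 transcripts was 2.36-fold higher in fresh water. The authors' deposited table calls each of these 4 transcripts. Of the 4 components, the last is the only one that met the 2-fold rule.

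The share of a component taken by each of its transcripts does not depend on the scaling between libraries. Of 14852 components with more than 1 transcript and at least 50 counts in each library, 914 (6.15%) had a transcript whose share moved by at least 50 percentage points. The component total of 103 of these 914 (11.3%) was at least 2-fold apart. The 12.6% of all components with at least 100 scaled counts over both libraries is not a like comparison. That set also includes components with 1 transcript and components with fewer than 50 counts in 1 library. The transcript with the most counts was a different one in the 2 libraries for 3456 components (23.3%). The files give no error for the division of reads between transcripts of a component, so these shares carry an uncertainty that the counting intervals leave out.

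More features were seen in brackish water alone than in fresh water alone. With at least 10 counts in 1 library and 0 in the other, 13213 transcripts were found in brackish water alone and 7079 in fresh water alone. Of these, 9234 of the brackish water set (69.9%) and 6697 of the fresh water set (94.6%) belonged to components with at least 10 counts in both libraries. At the level of components, 3867 were found in brackish water alone and 334 in fresh water alone. The brackish water components were short and of low abundance, with a median length of 266 bases and a median of 15 counts. The fresh water components had a median length of 232 bases and a median of 22 counts. With at least 50 counts, 60 components were found in brackish water alone and 41 in fresh water alone.

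The low counts of the 2 libraries also had different forms. Among components with 1 transcript, even counts made up 56.3% in fresh water (exact 95% interval 55.7 to 56.9) and 50.6% in brackish water (50.03 to 51.10). Components with 8 counts numbered 1330 in fresh water, against 979 with 7 and 956 with 9. In brackish water the same numbers were 1824, 1698 and 1870. Where reads are counted in pairs, the counting intervals given here are too narrow.

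**Figure D2:**
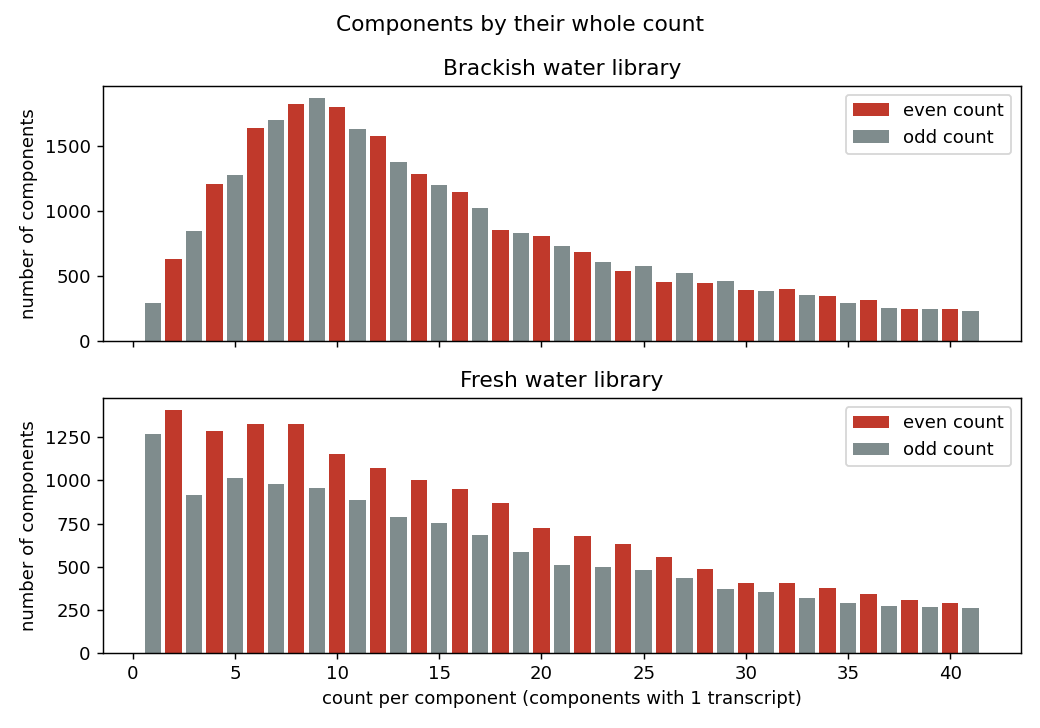
The number of components with 1 transcript (vertical axis) is plotted against their whole count from 1 to 41 (horizontal axis), for brackish water above and fresh water below, with even counts in red and odd counts in grey. In fresh water each even count from 2 to 40 stands above both of its odd neighbours, and brackish water shows no such alternation.

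The authors' deposited table covers 133434 transcripts and calls 297, of which 139 were higher in brackish water and 158 in fresh water. In the authors' deposited table, 46 of the called transcripts had a value of 0 in 1 library, 22 in fresh water and 24 in brackish water. The 297 calls of the authors' deposited table also met the 2-fold rule on scaled counts in the same direction. This is no independent check, since the calls already need a 2-fold ratio of FPKM in the same libraries. The called transcripts also had at least 165 counts in the higher library. Of the 297 transcripts, 194 (65.3%) belonged to a component that was 2-fold apart in the same direction, 88 higher in brackish water and 106 in fresh water. For 101 (34.0%) the component was not 2-fold apart, and for 2 it was 2-fold apart the other way. Only 162 of the 297 calls lay in components with more than 1 transcript, and all 101 were among these 162. The other calls are the only transcript of their component, so transcript and component are the same there. The 65.3% is therefore raised by calls that could not disagree.

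The calls lay among abundant transcripts. In the authors' deposited table, the higher FPKM of the called transcripts was at least 13.31, with a median of 82.0, against a median of 1.26 for all transcripts in it. Of the transcripts in it, 127749 (95.7%) had a higher FPKM below 13.31. Among those, the 2-fold rule on scaled counts called 26548, and the interval from counting error lay wholly beyond 2-fold for 19403.

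The p-values of that table followed FPKM and not the counts. In the authors' deposited table, 18650 sets of transcripts share both FPKM values, and all 18650 have a single p-value per set, although the brackish water count within a set differed by up to 114-fold where the FPKM was at least 1. A called transcript of 220 bases with 165 counts in brackish water and 0 in fresh water has an FPKM of 13.79 and a p-value of 0.000139 in the authors' deposited table. One of 3223 bases with 3286 counts and 0 in fresh water has an FPKM of 13.77 and a p-value of 0.000141 in the authors' deposited table.

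**Figure D3:**
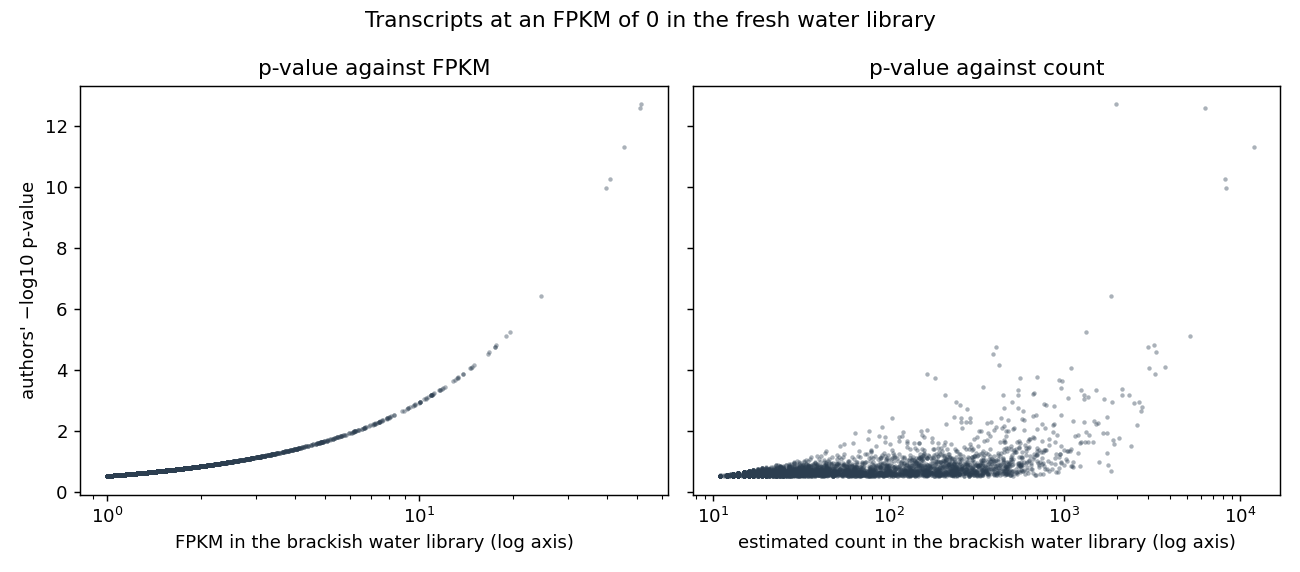
The −log10 p-value of the authors' deposited table (vertical axis) is plotted for 4112 transcripts at an FPKM of 0 in fresh water and of at least 1 in brackish water, against the brackish water FPKM on the left and the brackish water count on the right (log axes). Each point is a transcript. The points form 1 curve against FPKM and a wide cloud against the count; 1 transcript with a listed p-value of 0 is left out.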

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

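With 1 library per salinity, leaving out a library was not possible. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. The planned medians of gene lists, with their 4 alternatives, were not run, since no gene names were paired with the identifiers. Depth widens the counting intervals most for features with few counts, and the lack of replicates limits every comparison. The halved counts, the restriction to single-transcript components and the minimum on the sum of both libraries were chosen after the data had been seen.

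The number of transcripts 2-fold apart (27271, with 13692 higher in brackish water and 13579 in fresh water) stayed within 1.5 times under DESeq2 size factors, total count scaling, TPM ratios, a pseudocount of 5, an interval wholly beyond 2-fold (26285 at a pseudocount of 5, 20002 for the interval), and under a minimum of 100 scaled counts over both libraries (18854). Changing the scaling to DESeq2 size factors moved log2 folds by -0.02. The counts moved further with the minimum: 59176 (32573 and 26603) at 10 scaled counts, 9043 (4699 and 4344) at 200 and 69236 (39659 and 29577) without one, in each case because more or fewer features enter. They came to 14756 (7647 and 7109) at 4-fold, 6446 (2896 and 3550) with transcripts summed to components, 17402 (8998 and 8404) for an interval wholly beyond 2-fold with counts halved, and 4861 (2082 and 2779) in single-transcript components. The balance turned from brackish to fresh water in the sums over components, in single-transcript components, under DESeq2 size factors and under total count scaling (13495 against 13791 and 13615 against 13668), so no direction is drawn from it.

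Transcripts seen in brackish water alone fell from 13213 to 3862 at 50 counts and to 3867 when summed to components, and those in fresh water alone from 7079 to 3229 and 334. Changes of isoform share numbered 914, against 447 at 200 counts and 3668 at 25 percentage points. The authors' deposited table keeps 203 of its 297 calls at an FDR of 0.001, and all 297 had at least 50 scaled counts. By counts instead of TPM, the 10 most abundant transcripts took 19.5% in brackish water and 13.7% in fresh water, and the 100 most abundant 36.4% and 34.2%.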

Other observations

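The tests of pairs of mates by length and of thinning were set before their results were seen, and the other tests in this part were chosen after.

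In some components, different transcripts were at 0 in the 2 salinities. Among 14852 components with more than 1 transcript and at least 50 counts in each library, 748 held both a transcript with at least 50 counts in brackish water and 0 in fresh water and a transcript with at least 50 counts in fresh water and 0 in brackish water. Separately, 2533 components held the first kind and 2353 the second, and independent lists of these sizes would share 401.3. The totals of the 748 components had a median absolute log2 fold of 0.22, and 31 of them (4.14%) were at least 2-fold apart. That closeness is not particular to them, as the 13095 components with at least 1000 counts over both libraries had a median of 0.24. Needing at least 50 counts from such transcripts in each library also favours balanced totals. Since components with more transcripts can enter both lists more easily, the excess over independent lists was not tested further.

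Even counts outnumbered odd counts in fresh water but hardly in brackish water, so the low counts of the 2 libraries differ in form. The even share was 56.3% in fresh water, and this tally covered only components with 1 transcript. A candidate explanation is that both mates of a read pair were counted in fresh water, in which case the shortest transcripts should hold fewer complete pairs. The even share was 56.5% (exact 95% interval 55.1 to 57.8) at 400 bases or more and 54.5% (53.4 to 55.5) under 250 bases, and these intervals overlap. Between these classes it was 57.5% (56.7 to 58.4), above the shortest class beyond both intervals, but the share did not rise further in the longest class. The explanation stays open, as does duplication of fragments, which was not tested. No biological explanation was tested.

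Components found in brackish water alone (3867) outnumbered those found in fresh water alone (334). A deeper brackish water library stays open: its total was 0.993 times that of fresh water, but totals do not settle depth in fragments where the libraries may have been counted differently. An assembly from brackish water reads alone is argued against, since 41 components had at least 50 counts in fresh water and 0 in brackish water. Those 41 cannot speak to an assembly made mostly from brackish water reads, which was not tested and stays open. Components at 0 counts numbered 371 in brackish water and 5310 in fresh water. Counting of fresh water reads in pairs, at 2 reads per fragment, stays open. The brackish water counts were thinned to 50% in 20 draws to look at it. A mean of 745.8 components were then at 0 in brackish water while holding at least 10 counts in fresh water, fewer than the 3867. These include the 334 that were already at 0 before thinning. The thinning cannot decide the question, because it counts the reverse case in a set of components that nearly all held brackish water counts. The share at 0 in fresh water was 21.7% of components with 10 to 15 brackish water counts. It was 6.19% of those with 25 to 50 and 0.189% of those with 50 or more. In reverse, the shares of components at 0 in brackish water were 1.28%, 1.10% and 0.126% in the same classes of fresh water counts. Stronger duplication in fresh water, RNA or DNA from another source in the brackish water mixture, a different mixture of tissues, and salinity itself remain open and were not tested.

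The p-values in the authors' deposited table were a function of the 2 FPKM values, since 18650 of 18650 sets of transcripts that share both values had 1 p-value each. This is consistent with a test that took FPKM values in place of counts, and no biological explanation applies to it. Under such a test the length of a transcript decides how many reads a given p-value needs, as in the pair of called transcripts with 165 and 3286 counts. If so, the 297 calls may reflect abundance as well as the size of the difference.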
